A study of Mus musculus with 2 samples.

How the data were processed

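H3K27me3, the repressive histone H3 mark laid down by the Polycomb enzyme complex and found over silent developmental genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq). The tissue was the heart of mouse embryos of strain B6NCrl at embryonic day 10.5, with male and female embryos pooled, per the labels. There was 1 group with 2 biological replicates. Replicate 1 pooled hearts of 69 embryos and had 2 technical replicates, and replicate 2 pooled hearts of 51 embryos and had 3 technical replicates, per the labels. Fixed and sonicated chromatin went through a small-input ChIP protocol, per the labels' protocols.

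The authors deposited narrowPeak lists on mouse assembly mm10. Each replicate has its own list. A pooled list was called on the alignments of both replicates together, and a list of replicated peaks was derived from the other lists, per the deposited notes. The rule that kept a replicated peak, the aligner, the peak caller and the thresholds are not given in the sources used here. For every peak the authors deposited a fold enrichment of ChIP over control, which is a linear ratio. They also deposited a −log10 p and a −log10 q per peak. These values are the authors' own and were used here only to describe, rank or filter peaks within a list. The smallest −log10 p, before adjustment, was 2.02 in every list, so the lists include weak peaks. Alignments, control libraries and signal tracks were not used here.

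The peak lists hold no read totals, so the depth in reads is unknown. Relative depth was recovered from the fold and the −log10 p of each peak, as the whole number of overlapping fragments and the Poisson background that give both values when 1 is added to pileup and background. A peak counted as recovered when the −log10 p was met within 0.0002, which held for 100% of the peaks of either replicate. The most frequent background was 1.08 fragments in replicate 1, 5.27 in replicate 2 and 7.42 in the pooled list. The smallest peak width was 70 bp in replicate 1, 205 bp in replicate 2 and 180 bp in the pooled list. Divided by that width, the background was 0.0155, 0.0257 and 0.0412 fragments per bp, and the replicates summed to the pooled value with a ratio of 1. With one width for all lists the sum would be 0.857 times the pooled value. On the scale with separate widths replicate 2 was 1.66 times as deep as replicate 1, and with one width it would be 4.86 times.

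Genes and sequence came from GENCODE release M21 on GRCm38, the same build as mm10. The genome of chromosomes 1 to 19 and X without gaps is 2559 Mb, and 21728 protein-coding genes on it were used. A promoter was the window of 2 kb on each side of the gene's annotated 5′ end. It was called marked when merged replicated peaks covered at least 25% of the window. Peaks at most 3 kb apart were joined into domains, and domains of at least 20 kb were called broad. Bases were assigned to promoter, exon, intron or intergenic sequence in that order, and exons and introns were those of all annotated genes. The CpG content of a window was its observed over expected CpG ratio.

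Overlap of the replicates was measured as peaks sharing at least 1 bp and as the Jaccard index of covered bases. The Jaccard index and the classes of sequence were set beside 100 random placements of the peaks on their own chromosomes (bedtools 2.31.1, seed 20). Gene lists were tested with a two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. Intervals of shares are 95% exact Clopper-Pearson intervals and cover counting error only. CpG content was compared with a two-sided permutation test of 100000 resamples. The promoter rule, the lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes, from each list, up to 4 marked genes with the longest domains and up to 4 unmarked genes with the least covered windows. It takes all of either kind where 4 or fewer exist, plus the genes that start inside the 10 longest domains. Genes named beside these, such as neighbours of a domain that holds no gene start, were chosen after their values were seen. Tests between pairs of lists and the window coverage of Hox genes were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

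With 2 replicates of 1 group, no contrast between groups exists and no p-value across samples was computed. The p-values here are across genes, which are not independent replicates, since neighbouring genes can share a domain. The alternatives were other promoter windows (1 kb and 5 kb), other coverage minimums (any overlap and 50%), a stricter −log10 q of 2, any transcript start, the pooled list, each replicate's list alone, 1 gene per 100 kb, and 10000 random lists matched on CpG content. On simulated peaks, each centred on a gene start far from other starts, 0 of 918780 promoter calls were wrong. That setting fixed the outcome, so it checks the code and not calls from real peaks that are off-centre or shared by neighbours. Simulated lists of 18 promoters were called in 91.1% of trials at a true share of 60% marked against 20%, and in 3.33% of trials at a true share of 20%. All 19623 simulated pileups, made with the same formulas that the recovery inverts, were recovered.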

Results

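H3K27me3 peaks were available for 2 pooled-tissue replicates of the mouse heart at embryonic day 10.5, a stage when the looped heart tube forms chambers, cushions and the outflow tract. The tissue holds cardiomyocytes together with endocardial, epicardial, cushion and blood cells, so a promoter can be marked in part of the cells. Replicate 1 had 232346 peaks with a median width of 103 bp, covering 35.8 Mb or 1.40% of the genome. Replicate 2 had 155369 peaks with a median width of 329 bp, covering 90.0 Mb or 3.52%. The replicated list had 76696 peaks with a median width of 565 bp, covering 75.5 Mb or 2.95%. The authors' fold enrichment over control had a median of 3.32 in replicate 1, 2.74 in replicate 2 and 3.08 in the replicated list. A −log10 q of 2 or more was reached by 18.4% of the replicate 1 peaks, 77.9% of the replicate 2 peaks and 97.8% of the replicated peaks. The read depth is unknown, and replicate 2 was 1.66 times as deep as replicate 1 on the recovered scale.

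**Figure D1:**
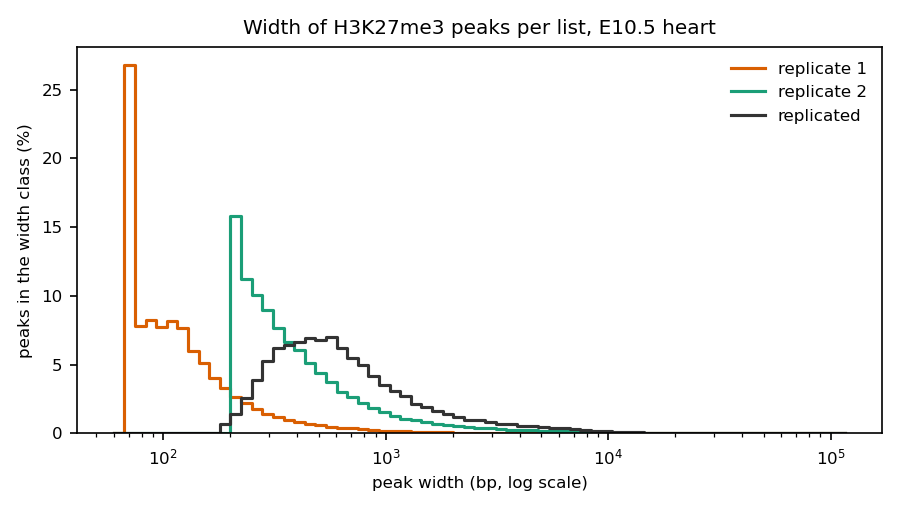
Distribution of peak width in bp (log axis) against the percent of peaks in each width class, for replicate 1, replicate 2 and the replicated list, with lines for the lists. The median is 103 bp in replicate 1, 329 bp in replicate 2 and 565 bp in the replicated list.

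The comparison of the replicates asks how far the same regions carried the mark in separate pools of hearts. Peaks of both replicates covered the Hox clusters and all listed promoters of neural and limb regulators, and replicate 2 marked more genes than replicate 1. Of the genes marked from replicate 1 peaks, 2387 of 2390 (99.9%) were also marked from replicate 2 peaks, where independent lists would share 487. Replicate 2 marked 4428 genes, so 53.9% of its genes were also marked in replicate 1. By peak, 53.2% of the replicate 1 peaks and 38.2% of the replicate 2 peaks overlapped a peak of the other replicate. They shared 23.6 Mb, which was 65.9% of the bases in replicate 1 peaks and 26.2% of those in replicate 2 peaks. The Jaccard index was 0.231, which is 20.6 times the mean of 0.0112 over 100 random placements, whose values ran from 0.0106 to 0.0119. Every replicated peak had the interval of a pooled peak, and 37.1% of the pooled peaks were kept. A replicate 2 peak overlapped 95.1% of the replicated peaks by at least 1 bp and a replicate 1 peak 78.9%. At least 50% of the length was covered by replicate 2 peaks in 88.8% of the replicated peaks and by replicate 1 peaks in 10.8%.

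H3K27me3 formed long blocks over the Hox clusters and other loci. Joined replicated peaks gave 26479 domains with a median length of 1173 bp, against 796 bp in 42846 domains without replicate 1 and 122 bp in 69375 domains without replicate 2. Of these, 1058 were at least 20 kb long and held 39.6 Mb, or 34.9% of the domain length. The number of such domains depended on the joining gap, with 419 at 1 kb and 2385 at 10 kb, and was 1701 without replicate 1. The longest domain, 314 kb on chromosome 8 (120791773 to 121106163, mm10), ended past Foxf1, a forkhead factor of the splanchnic mesoderm. Of its bases, 93.5% were intronic because the annotation places the long gene Gm20388 across it. The HoxC cluster lay in a domain of 265 kb on chromosome 15 (102893566 to 103158938) that held 9 Hoxc genes. The HoxA cluster with Evx1 lay in 187 kb on chromosome 6 (52145837 to 52332987), and Hoxb1 to Hoxb9 lay in 155 kb on chromosome 11 (96230702 to 96385368). A domain of 203 kb on chromosome 2 (165066500 to 165269566) held the start of Cdh22, a cadherin gene, and of 1700025C18Rik. A domain of 168 kb on chromosome 4 (136817190 to 136985279) held the ephrin receptor genes Ephb2 and Epha8 and, between them, the complement genes C1qa, C1qb and C1qc. The start of Sipa1l3 lay in 155 kb on chromosome 7 (29368862 to 29524096), with 92.2% of bases in introns. Rhcg, an ammonium transporter gene, started in 134 kb on chromosome 7 (79486352 to 79620718). A domain of 146 kb on chromosome 2 (168436290 to 168582718) lay over Nfatc2 without reaching its annotated start, 18.9 kb away. The remaining domain, 136 kb on chromosome X (99477090 to 99613568), was entirely intergenic and lay 5.82 kb from the start of Pja1. Replicate 2 peaks covered 58.5% to 94.8% of each of these 10 domains. Replicate 1 peaks covered 14.5% of the domain on chromosome X and 20.9% to 68.0% of the others.

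The mark was concentrated at promoters and exons. Promoter windows held 16.3% of the replicated peak bases against 3.16% of the genome, a 5.16-fold excess, where random placement gave 1.04-fold to 1.16-fold. The excess was 5.73-fold in replicate 1 and 4.47-fold in replicate 2. Exons outside promoters were covered 2.09 times as often as their share of the genome, introns 0.986 times and intergenic sequence 0.664 times. The intron value was 1.06 with promoters of 1 kb on each side, so its direction depended on the window. Marked promoters had a median CpG observed over expected ratio of 0.416 against 0.354 in unmarked ones. The difference of 0.0627 had a permutation p of 1e-05, the smallest that 100000 resamples can give (4272 against 17456 promoters). Across the deciles of CpG content, 1.06% of promoters were marked in the lowest decile, 30.6% in the fifth and 20.1% in the highest.

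Chromosome 11, which carries the HoxB cluster, was covered most among the autosomes and chromosome 3 least, in both replicates. Replicated peaks covered 5.45% of chromosome 11 and 1.33% of chromosome 3, with a median of 3.11% over the 19 autosomes. They covered 2.26% of chromosome X, or 0.728 times the autosome median. The replicates differed on X. Replicate 1 peaks covered 0.480% of X, below every autosome (lowest 0.709%, median 1.54%), and replicate 2 peaks covered 3.91% against an autosome median of 3.59%. Of 948 genes on X, 35 (3.69%) were marked in replicate 1 and 250 (26.4%) in replicate 2, against 11.3% and 20.1% of autosomal genes. By covered bases, X thus lay below the autosome median in replicate 1 and above it in replicate 2. By the share of 100 kb bins that hold a peak, X lay below the autosomes in both. That share was 36.2% against 63.7% in replicate 1 and 36.3% against 47.5% in replicate 2.

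**Figure D2:**
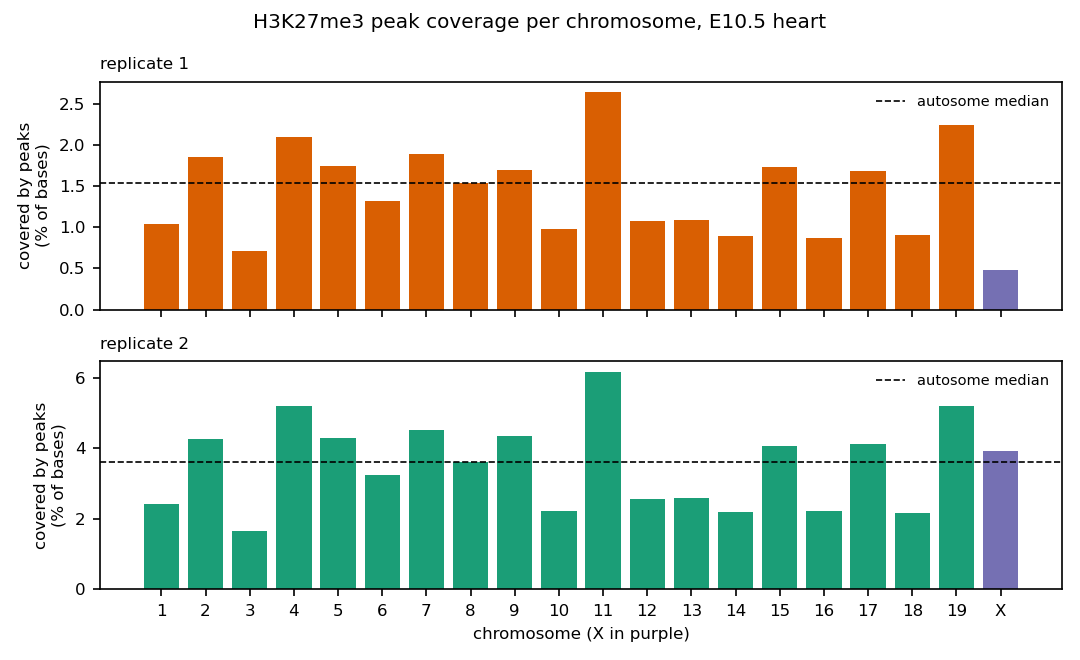
Percent of bases covered by H3K27me3 peaks on each chromosome (autosomes 1 to 19, and X in purple) for replicate 1 above and replicate 2 below, with a dashed line at the autosome median. Bars for X stand at 0.480% in replicate 1 and 3.91% in replicate 2, and among the autosomes chromosome 11 is highest and chromosome 3 lowest in both.

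The gene lists ask which developmental programmes carried the mark at their promoters in the heart. In all, 4272 of 21728 protein-coding genes (19.7%) had a marked promoter, with 3409 ± 1441 (SD, n = 2) from the replicates' own lists and 699 windows fully covered. Without replicate 2, the count was 2390. Of the 24 lists, 18 were marked more often than other genes, 2 less often, and 4 did not pass the test. The share per list, from the replicated list and from each replicate, is shown in the plot of gene lists.

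**Figure D3:**
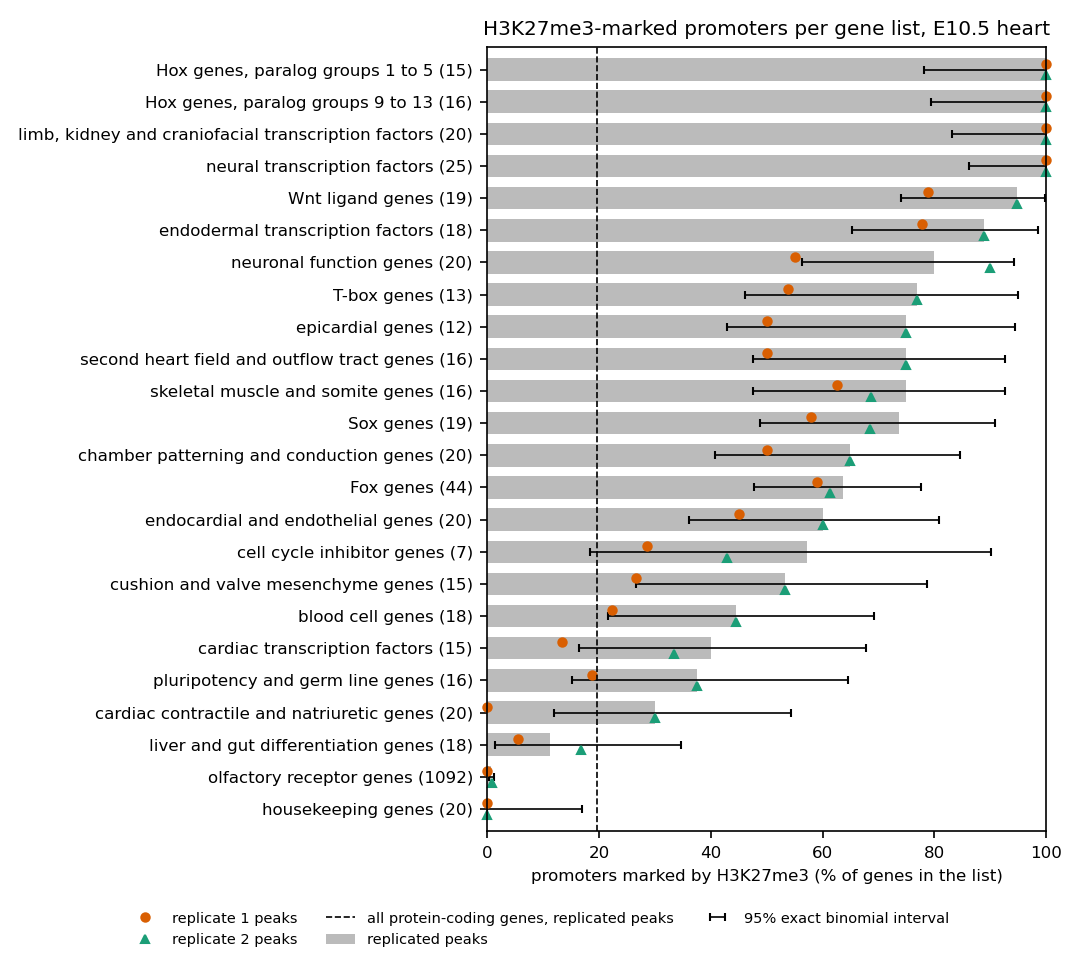
Percent of genes with an H3K27me3-marked promoter in each of 24 gene lists (members in parentheses). Grey bars are the replicated peaks with 95% exact binomial intervals, circles replicate 1, triangles replicate 2, and the dashed line the 19.7% of all protein-coding genes. Neural, limb and Hox lists stand at 100% and housekeeping genes at 0%.

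Among genes that build and run heart muscle, most promoters were not marked. Of 15 cardiac transcription factors, 6 were marked, and the replicates' own lists gave 23.3% ± 14.1 (SD, n = 2). Replicate 1 marked 2 of the 15 and replicate 2 marked 5, so neither replicate alone made all 6 calls. Hand1 had 100% of its promoter covered at a highest fold of 6.35, and Tbx20 had 25.02%, just above the 25% minimum for a call. Nkx2-5, the homeobox factor of cardiac progenitors, had 75.6% of its promoter covered (41.5% in replicate 1, 78.1% in replicate 2) at a highest fold of 7.12. Gata4, a zinc finger factor of heart muscle, had 67.8% covered, and Tbx5, a T-box factor of atria and left ventricle, had 77.2%. Hand2, a helix-loop-helix factor of the right ventricle, had 39.6% covered, but 0% of its central 1 kb. In replicate 1 these values were 17.7% for Gata4, 19.2% for Tbx5 and 3.95% for Hand2, all below the minimum for a call. Gata6, Mef2a, Mef2c and Mef2d had 0% covered by replicated peaks, although another annotated start of Gata6 had 28.3%. Of 20 contractile and natriuretic genes, 6 (30.0%) were marked, with 0 in replicate 1 and 6 in replicate 2. Myl7, an atrial light chain gene, had 55.5% of its promoter covered, and Ryr2, the calcium release channel gene, had 46.7%. Myl3 had 38.3% and Tnni1, the slow troponin I gene, 32.6%. The promoters of Myh6 and Myh7, which encode the myosin heavy chains of heart muscle, and of Tnnt2 and Tnnc1, which encode troponins, had 0% covered by replicated peaks, although pooled peaks covered 25.6% of the Myh7 promoter, enough for a call. Neither list passed Fisher's exact test (cardiac factors 2.04 times the 19.6% of other genes, adjusted p = 0.108, and contractile genes 1.53 times, adjusted p = 0.270). Windows of 5 kb on each side brought the cardiac factors to 2.36 times by Fisher's exact test (adjusted p = 0.0355, range 0.0355 to 0.707 over the alternatives) and turned the contractile genes to 0.885 times. Without replicate 2 the ratios were 1.21 and 0.

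Genes that pattern chambers, the conduction system and the outflow tract were marked more often than other genes. Of 20 chamber and conduction genes, 13 (65.0%) were marked, 10 from replicate 1 and 13 from replicate 2. Tbx2 and Tbx3, repressors of the chamber programme in the atrioventricular canal and conduction system, lay in domains of 89.5 kb (chromosome 11, 85761092 to 85850588) and 81.9 kb (chromosome 5, 119615153 to 119697019). Pitx2, the left-right asymmetry factor, lay in 40.1 kb and Irx5 in 31.5 kb. The connexin genes Gja1 and Gja5, the ventricular factor Hey2 and the trabecular growth factor Bmp10 had 0% covered, although another annotated start of Gja5 had 55.3%. Of 16 second heart field and outflow tract genes, 12 were marked, 8 from replicate 1 and 12 from replicate 2. Foxf1 and Fgf8, a growth factor of pharyngeal mesoderm, had 100% and 94.5% of their promoters covered, Foxc1 had 94.9% and Six1 had 78.6%. Fgf10, Eya1, Wnt5a and Sema3c were unmarked, although another annotated start of Fgf10 had 46.2%. The ratios to other genes were 3.31 for chamber genes (Fisher's exact test, adjusted p = 2.28e-05) and 3.82 for outflow genes (Fisher's exact test, adjusted p = 5.40e-06).

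**Figure D4:**
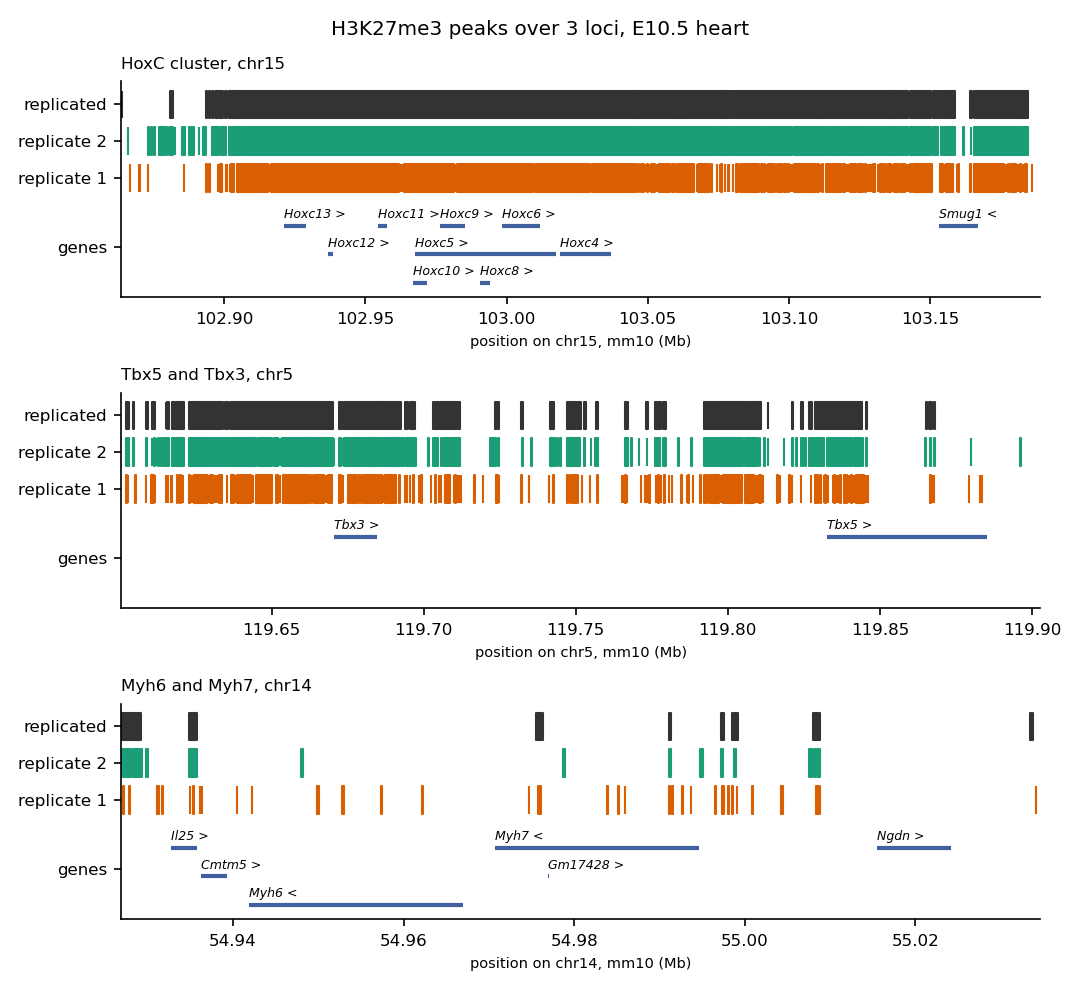
H3K27me3 peaks along 3 loci (position in Mb, mm10), with replicated, replicate 2 and replicate 1 peaks as bars in black, green and orange and protein-coding genes in blue with their strand. The HoxC cluster is covered from end to end, Tbx3 and Tbx5 lie in separate domains, and the starts of Myh6 and Myh7 lie outside replicated peaks.

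Lists of other cell types of the heart were also marked more often than other genes. Among 20 endocardial and endothelial genes, 12 were marked, 9 from replicate 1 and 12 from replicate 2. The factors Nfatc1 (99.6% of the promoter covered), Sox17 (94.8%), Erg (91.5%) and Fli1 (72.0%) were marked, while the surface protein genes Pecam1, Cdh5, Tek and Tie1 had 0% covered. The 12 marked genes outnumber the transcription factors on the list, so marking was not confined to factors. Among 12 epicardial genes, 9 were marked (6 from replicate 1, 9 from replicate 2), with Wt1 at 98.1%, Bnc1 at 100%, Tbx18 at 78.4% and Msln at 45.8% (7.35% in replicate 1). Upk1b, Upk3b and Krt19 were unmarked, although another annotated start of Krt19 had 73.0% covered. Among 15 cushion and valve genes, 8 (53.3%) were marked, with Msx1 at 92.2%, Twist1 at 91.3%, Msx2 at 89.6% and Sox9 at 59.5%. Replicate 1 marked 4 of the 15 and replicate 2 marked 8, and Twist1 (17.6%) and Sox9 were below the minimum in replicate 1. Postn, Has2, Tgfb2 and Prrx2, of which the first encodes a matrix protein and the next a hyaluronan synthase, had 0%. Among 18 blood cell genes, 8 (44.4%) were marked, with Tal1 at 95.6%, Runx1 at 91.3%, Klf1 at 73.5% and Lmo2 at 45.8%. Replicate 1 marked 4 of the 18 and replicate 2 marked 8, and Runx1 (24.4%), Klf1 (13.7%) and Lmo2 (10.5%) were below the minimum in replicate 1. The embryonic globin genes Hbb-y and Hbb-bh1 and the factors Gata1 and Spi1 had 0%. The ratios were 3.06 for endocardial genes (Fisher's exact test, adjusted p = 0.000127) and 3.82 for epicardial genes (Fisher's exact test, adjusted p = 8.58e-05). They were 2.72 for cushion genes (Fisher's exact test, adjusted p = 0.00534) and 2.26 for blood genes (Fisher's exact test, adjusted p = 0.0196). Without replicate 2, cushion genes (adjusted p = 0.105) and blood genes (adjusted p = 0.171) no longer passed Fisher's exact test.

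Regulators of other organs were marked more often than other genes, and those of the neural and limb, kidney and craniofacial lists without exception. All 25 neural transcription factors were marked in each replicate and in the replicated list (95% interval 86.3% to 100%). En2 and Lmx1b, midbrain and hindbrain patterning genes, lay in domains of 110 kb (chromosome 5, 28107591 to 28217924) and 99.3 kb (chromosome 2, 33554267 to 33653591). Neurog1, a neuronal determination gene, lay in 65.3 kb and Gbx2 in 62.2 kb. All 20 genes of the limb, kidney and craniofacial list were marked in each replicate. That list holds the ligand genes Shh and Ihh beside transcription factors. Ihh, Tbx4, Six2 and Pax2 had promoters covered by 100%. Of 18 endodermal factors, 16 were marked (14 from replicate 1, 16 from replicate 2), and Hnf4a and Prox1 were not, although another annotated start of Hnf4a had 80.4% covered and pooled peaks covered 29.3% at Prox1. Pdx1 and Cdx2, factors of pancreas and intestine, shared a domain of 66.0 kb on chromosome 5 (147260680 to 147326682). Nkx2-3 lay in 65.2 kb, and Ptf1a, a pancreas factor, reached a fold of 17.7. Of 16 skeletal muscle and somite genes, 12 were marked (10 from replicate 1, 11 from replicate 2), with Pax7 in a domain of 129 kb (chromosome 4, 139734115 to 139863464), Pax3 in 94.2 kb, Uncx in 84.5 kb and Myod1 in 52.5 kb. Myf5, Myf6, Tbx6 and Msgn1 were unmarked. The ratios were 5.11 for neural factors (Fisher's exact test, adjusted p = 2.48e-17) and 5.11 for limb, kidney and craniofacial genes (Fisher's exact test, adjusted p = 5.75e-14). They were 4.53 for endodermal factors (Fisher's exact test, adjusted p = 1.49e-09) and 3.82 for muscle and somite genes (Fisher's exact test, adjusted p = 5.40e-06). Fewer genes were marked in all without replicate 2. The ratios were then 9.18 for neural factors, 9.16 for limb, kidney and craniofacial genes and 7.11 for endodermal factors.

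Among genes for the differentiated functions of other organs, neuronal function genes were marked more often than other genes, and liver and gut genes did not pass the test. The difference between these lists was not tested. Of 20 neuronal function genes, 16 (80.0%) were marked, 11 from replicate 1 and 18 from replicate 2. They included Grin1, a glutamate receptor gene with 100% of its promoter covered, Slc17a7 with 87.0%, Th, the rate-limiting enzyme of catecholamine synthesis, with 71.7% (16.4% in replicate 1), and Rbfox3 with 53.1%. Snap25, Stx1a, Map2 and Gad1 were unmarked, although another annotated start of Gad1 had 100% covered. Replicate 2 and pooled peaks passed the minimum at Map2 (26.5% from pooled peaks) and Gad1 (28.0% from pooled peaks). Of 18 liver and gut differentiation genes, 2 (11.1%) were marked, the mucin gene Muc2 and the stem cell gene Lgr5, with 1 from replicate 1 and 3 from replicate 2. The promoters of Alb, Afp, Apob and Ttr, which encode secreted liver proteins, had 0%. Neuronal function genes were marked 4.08 times as often as other genes (Fisher's exact test, adjusted p = 2.79e-08). Liver and gut genes were at 0.565 times other genes (Fisher's exact test, adjusted p = 0.554), and with windows of 1 kb on each side 4 of 18 were marked, at 1.18 times other genes. The direction of that list therefore depended on the window, and with windows of 5 kb the ratio was 0.983.

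Cardiac lists were marked less often than lists of other organs in 4 of 5 tests between lists, all chosen after the list results were seen. The tests compare the lists as written, without matching on CpG content or on the kind of gene. The 6 marked cardiac factors were Nkx2-5, Gata4, Tbx5, Tbx20, Hand1 and Hand2, and the unmarked ones included Mef2a, Mef2d, Srf and Tead1. The differences can thus reflect which genes were put on each list. Cardiac transcription factors (6 of 15) were marked less often than neural factors (25 of 25; Fisher's exact test, adjusted p = 9.15e-05). They were also marked less often than limb, kidney and craniofacial genes (20 of 20; Fisher's exact test, adjusted p = 0.000177) and endodermal factors (16 of 18; Fisher's exact test, adjusted p = 0.00975). Contractile genes (6 of 20) were marked less often than neuronal function genes (16 of 20; Fisher's exact test, adjusted p = 0.00607). Contractile genes did not differ detectably from liver and gut genes (2 of 18; Fisher's exact test, adjusted p = 0.238). In each of the 4 contrasts that passed, the cardiac list had the lower share in both replicates.

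The listed families of signalling and transcription factor genes, Wnt, Fox, Sox and T-box, were marked above other genes. That did not hold for every such family, since Zfp zinc finger genes were below other genes (29 of 394). Of 19 Wnt ligand genes, 18 were marked and Wnt5a was not (15 from replicate 1, 18 from replicate 2). Wnt7a lay in a domain of 94.1 kb on chromosome 6 (91331441 to 91425511), Wnt6 and Wnt10a shared 55.4 kb, and Wnt3 lay in 50.5 kb. Of 44 Fox genes, 28 were marked (26 and 27), including Foxd2 and Foxe3 in a shared domain of 66.0 kb and Foxo6 in 57.3 kb, while Foxj2, Foxj3, Foxk1 and Foxk2 had 0%. Of 19 Sox genes, 14 were marked (11 and 13), including Sox1 in 60.1 kb, Sox2 in 45.8 kb and Sox14 in 28.8 kb, while Sox4, Sox11, Sox12 and Sox15 had 0%. Of 13 T-box genes, 10 were marked (7 and 10), including Tbx4 and Tbx21, and Tbx6, Tbx19 and Tbx22 were not, although another annotated start of Tbx22 had 72.1% covered. At Tbx19, replicate 2 peaks covered 26.6% and pooled peaks 33.4%. The ratios were 4.83 for Wnt genes (Fisher's exact test, adjusted p = 1.74e-11) and 3.25 for Fox genes (Fisher's exact test, adjusted p = 7.83e-10). They were 3.76 for Sox genes (Fisher's exact test, adjusted p = 1.29e-06) and 3.92 for T-box genes (Fisher's exact test, adjusted p = 2.33e-05). Without replicate 2 the ratio of Fox genes was 5.42.

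Genes used in all cells and receptor genes of the nose lay at the other end. None of the 20 housekeeping genes, Gapdh, Hprt, Tbp and Ppia among them, was marked in either replicate, which allows a share of up to 16.8% (exact interval). That was below other genes by Fisher's exact test (adjusted p = 0.0270), but the exact test gave an adjusted p of 0.190 without replicate 2, 0.175 with windows of 1 kb (1 of 20 marked), 0.101 with any overlap (2 of 20) and 0.118 with at least 50% of the window covered. Of 1092 olfactory receptor genes, 6 (0.549%) were marked, Olfr71, Olfr222, Olfr94 and Olfr1377 among them, with 0 from replicate 1 and 8 from replicate 2, and neither replicate's own list called Olfr222 (ratio 0.0266; Fisher's exact test, adjusted p = 3.78e-94). The median CpG ratio of their promoters was 0.112, and against random lists matched on CpG content, whose genes were marked at 5.06%, the ratio was 0.108. With at least 50% of the window covered, or without replicate 2, 0 were marked. Of 16 pluripotency and germ line genes, 6 (37.5%) were marked, 3 from replicate 1 and 6 from replicate 2, including Pou5f1 with 100% of its promoter covered, Prdm14 with 97.0%, Nanog with 81.9% and Tdrd1 with 77.0% (13.7% in replicate 1). Zfp42, Dppa4, Dazl and Sycp3 had 0%, and the list did not pass Fisher's exact test (ratio 1.91, adjusted p = 0.116). Of 7 cell cycle inhibitor genes, 4 were marked (2 from replicate 1 and 3 from replicate 2). Cdkn2a and Cdkn2b shared a domain of 46.0 kb on chromosome 4 (89267878 to 89313865). Cdkn1a had 51.2% of its promoter covered and Cdkn1c 37.2%, but neither replicate's own list called Cdkn1c (18.9% in replicate 1, 19.3% in replicate 2) and replicate 1 did not call Cdkn1a (15.7%), while Cdkn1b, Cdkn2c and Cdkn2d were unmarked, although another annotated start of Cdkn2c had 66.1%. The ratio was 2.91 (Fisher's exact test, adjusted p = 0.0377), and without replicate 1 the exact test gave an adjusted p of 0.177 and without replicate 2 one of 0.20. The exact test also missed the threshold with at least 50% of the window covered (adjusted p = 0.0748), the pooled list (0.0602) and 1 gene per 100 kb (0.0551), as did the random lists matched on CpG content (adjusted p = 0.0823).

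The Hox genes were compared by position, since anterior Hox genes are used by cells that enter the outflow region of the heart and posterior ones belong to the trunk and limbs. All 15 genes of paralog groups 1 to 5 and all 16 genes of groups 9 to 13 were marked, in the replicated list and in each replicate. The shares were equal (Fisher's exact test, p = 1), which leaves no room to tell the groups apart by calls. Each list differed from other genes (ratio 5.10 for both; Fisher's exact test, adjusted p = 9.95e-11 for groups 1 to 5 and 2.34e-11 for groups 9 to 13). The exact test counts each gene as separate, although genes of the same cluster mostly share a domain, so these p-values overstate the evidence. Without replicate 2 the ratios were 9.14 and 9.15. From the first to the last gene start, replicated peaks covered 99.3% of the HoxA cluster, 87.3% of HoxB, 99.9% of HoxC and 97.6% of HoxD (chromosome 2, 74668310 to 74765142). In replicate 1 these shares were 69.8%, 63.2%, 88.1% and 70.9%. By covered share of the window, replicate 1 had 83.7% ± 8.69 (SD, n = 16 genes) for groups 9 to 13 and 70.8% ± 15.5 (SD, n = 15 genes) for groups 1 to 5. The difference of 12.9 percentage points had a permutation p of 0.00818 (0.0245 adjusted over 3 tests). Among the anterior genes, Hoxb2 had 46.4% and Hoxa2 49.3%, but Hoxc5 had 95.7% and Hoxc4 97.0%. The p treats windows as independent, which they are not. Hoxc5 and the posterior Hoxc10 (93.8%) have annotated starts so close that their windows largely overlap. HoxC, the best covered cluster in replicate 1, gave more posterior than anterior genes, so cluster and position are mixed in this difference. In replicate 2 both groups were nearly fully covered, with means of 98.9% and 99.1%, and the difference of −0.24 points had a permutation p of 0.756. In the replicated list the difference was −0.34 points (permutation p = 0.557).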

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

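No paired analysis was possible because the series has 1 group. Of 264 tests of gene lists under alternatives, 248 kept their direction and side of the threshold, 12 lost significance, 1 gained it and 3 reversed without being past the threshold in either case. The gain was cardiac transcription factors with windows of 5 kb (ratio 2.36, Fisher's exact test, adjusted p = 0.0355). Liver and gut genes reversed with windows of 1 kb (1.18), and contractile genes with windows of 5 kb (0.885) and without replicate 2 (0 to 1.47 with single replicates). Housekeeping genes lost significance with windows of 1 kb (0.266), with any overlap (0.361) and with at least 50% of the window (0), and without replicate 2 (the ratio was 0 with either replicate alone). Cell cycle inhibitors lost it with 50% of the window (3.12), the pooled list (2.53), 1 gene per 100 kb (2.60), matching on CpG (2.78) and either replicate alone (2.10 to 2.60). Cushion genes had ratios of 2.43 to 2.62 and blood genes of 2.02 to 2.18 with single replicates, and both lost significance without replicate 2. Among named promoters, 34 calls were lost under an alternative, 25 of them without replicate 2, and 21 were gained. Leaving out a replicate gave 155369 to 232345 peaks, 42846 to 69375 domains, 1085 to 1701 broad domains, 2390 to 4428 marked genes and X coverage of 0.312 to 1.09 times the autosome median, reversed without replicate 1. Gaps of 1 kb and 10 kb gave 40729 and 15363 domains, of which 419 and 2385 were broad. Replicate overlap moved with −log10 q of 2 or more (Jaccard index 0.161, 83.7% of replicate 1 and 13.3% of replicate 2 peaks) and with equal numbers of top peaks (0.214, 61.4% and 29.6%). Requiring 50% of the peak's length gave 49.0% and 6.33%. Promoters of 5 kb gave folds of 4.01 for promoters, 1.74 for exons, 0.855 for introns and 0.596 for intergenic sequence, and promoters of 1 kb gave 2.30 for exons and 1.06 for introns, the last reversed. These changes came with the window that defines the promoter class. The cause of these and of the other changes was not tested. Read totals are unknown, so what depth limits in each list could not be measured.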

Other observations

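The scan of gene families, the ranking of single peaks, and the tests of peak width and of recovered backgrounds below were chosen after the results were seen. The bound for the test of bare start sites was written before, but its margin of 1 SD was chosen after the value was seen, and with no margin or 1 standard error the value would count against that explanation.

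A scan of 356 families of genes sharing a symbol stem, with at least 8 members each, found 39 families marked more often and 18 less often than other genes. All 14 Nkx genes, all 9 Pax genes and all 8 Lhx genes, homeobox and paired-box regulators of regional identity, were marked (Fisher's exact test, adjusted p = 7.52e-09, 1.29e-05 and 4.07e-05). The families marked more often also included 8 of 8 Grm glutamate receptor genes, 8 of 8 Kcnh potassium channel genes, 12 of 14 Htr serotonin receptor genes and 13 of 17 Syt synaptotagmin genes, while 3 of 9 Chrna acetylcholine receptor genes and 6 of 14 Scn sodium channel genes did not pass Fisher's exact test (adjusted p = 0.565 and 0.145). Fgf growth factor genes were marked at 15 of 22, Col collagen genes at 21 of 45 and Krt keratin genes at 23 of 53. At the other end were 0 of 330 Vmn pheromone receptor genes, 29 of 394 Zfp zinc finger genes, 1 of 67 Hist histone genes, 0 of 49 Mrpl mitochondrial ribosomal genes and 0 of 42 Defb defensin genes (Fisher's exact test, adjusted p = 4.95e-30, 6.91e-10, 0.000258, 0.000516 and 0.00167).

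The 10 single peaks with the highest fold included peaks at genes of neurons, the pancreas and hormone metabolism. The peak at Neurog3, an endocrine pancreas factor, had a fold of 18.5 (chromosome 10, 62125601 to 62139338), and a peak inside Rbfox3 had 17.9 (chromosome 11, 118566617 to 118574958). Peaks at Ptf1a (17.7) and Neurod2 (15.6) followed, and Dio3, a thyroid hormone deiodinase, had 15.6 (chromosome 12, 110266841 to 110287443). Next came Hr, a hair cycle corepressor, at 15.5. Replicate 1 peaks covered 63.3% to 93.8% of the 10 highest peaks and replicate 2 peaks 97.3% to 100%.

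Replicate 1 had more peaks than replicate 2, but they were short, and fewer of them reached a −log10 q of 2 (18.4% against 77.9%), although their median fold was higher (3.32 against 2.74). Lower depth of replicate 1 alone was argued against by the smallest peak width, which was 2.93 times larger in replicate 2 (205 bp against 70 bp), a bound that depth does not set. A shorter fragment window in the peak calling of replicate 1 may account for the short peaks, since the median width over the smallest width differed by 1.09 times between replicates while median widths differed by 3.19 times. One window for all lists was argued against, since the recovered replicate backgrounds summed to 0.857 times the pooled one with a common width and to 1 with separate widths. Why the windows differed is open, and no biological explanation was tested.

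Little of chromosome X was covered in replicate 1. Lower detection power on all chromosomes was argued against, since replicate 1 overlapped 21.4% of replicate 2 peaks on X, against 36.7% to 41.5% on the autosomes after matching on −log10 p and width. A different share of male and female embryos in the pools could give such a difference, because an inactive X carries the mark and a male has a single X. The shares are not given in the labels, and that explanation was not tested.

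Promoters of heart transcription factors were called marked in a heart sample. A mark confined to cells of the heart that do not use the gene would lower the enrichment, and the highest fold was 4.60 ± 1.79 (SD, n = 6) at marked heart factors against 8.80 ± 2.42 (SD, n = 25) at neural factors. The difference of −4.20 (exact permutation p = 8.15e-05) went the way that hypothesis predicts, though partial silencing within all cells would look alike. It cannot single out that hypothesis, because neural factors were the only comparison. A low fold was also not particular to heart factors, since the marked liver and gut genes Muc2 and Lgr5 had highest folds of 3.63 and 4.35. Peaks in the flanks with a bare start site were tested by the central 1 kb, covered by 70.0% ± 41.5 (SD, n = 6) at heart factors. That was less than the 99.5% at neural factors (difference −29.5, exact permutation p = 0.0089). The mean met the bound of 50% that was written before as counting against a bare start site. It did so by less than 1 SD, and the genes differed, so the explanation stays open for the 6 genes as a set. The central 1 kb was covered by 100% at Gata4, Nkx2-5 and Hand1, so the annotated 5′ ends used here were not bare. It was covered by 80.4% at Tbx5, 39.7% at Tbx20 and 0% at Hand2. Whether other annotated starts of these genes were bare was not tested.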
